A study of Oncorhynchus mykiss with 20 samples.

How the data were processed

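Gill tissue of 20 rainbow trout (Oncorhynchus mykiss) was profiled by RNA sequencing, with 10 fish labelled control and 10 labelled infected. Per the labels' protocols, total RNA was extracted from homogenized gill, treated with DNase, checked for integrity and made into libraries with a stranded mRNA kit, and the series' design text names an Illumina HiSeq2500. The deposited values are raw read counts per gene, whole numbers that the authors did not scale, given once per library and once as a table of the whole series. Both versions held the same counts in 20 of 20 libraries. CASAVA, TopHat2 2.0.5, SAMtools 0.1.18, HTSeq 0.5.3p9 and DESeq are named, with no role or order, per the submitters' processing notes. The genome build, the strand setting of the counting and the treatment of reads with several alignments are not given in the sources used here. The summary line for reads without a unique alignment stood at 0 in every library.

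The authors deposited a gene annotation with 46585 gene models, which held all 46585 genes of the count table. Its positions and its score column come from the Gaze gene predictor, per the file's source column, and the deposited score was not used as a measurement. The annotation places 21576 gene models on a sequence called chrUn and 25009 on sequences whose names carry a chromosome, of which 2336 lie on sequences named chr_ and 22673 on sequences named chrUn_ followed by the chromosome. What the chrUn_ prefix stands for is not given in the sources used here, and if such sequences are joined from scaffolds, genes next to each other in them need not be neighbours in the genome. In the annotation, 48 models start inside an earlier one. Coding lengths were multiples of 3 in 46566 models. No gene ID matched the reference name table of 72772 genes, and the deposited files do not pair IDs with names. Gene lists chosen before the data were examined (immune pathways, gill cell types, blood, stress and repair) were therefore not tested, and genes are given by ID. The rule for named genes, set before the data were examined, falls back in that case to the 2 genes that rose and the 2 that fell with the smallest adjusted p among genes with a mean of at least 5 CPM (normalized counts scaled to the library size). Near-identical gene copies could not be looked for without sequences, so values of single genes carry the uncertainty of reads shared between copies.

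Lines that name no gene stayed out of library sizes and tests. Of the reads counted in or outside genes, 40.4% ± 7.42 (SD, n = 10) lay outside annotated genes in control fish and 33.8% ± 1.33 (SD, n = 10) in infected fish, and reads that overlapped more than 1 gene made up 0.0568% and 0.0569%. Reads in genes numbered 5692204 to 10498985 per library. The counts of libraries of 1 group differed beyond sampling noise in every pair, with a lowest chi-square of 8.41 per degree of freedom, so no library was counted as a duplicate. The labels number the fish but do not say how they were kept, and p-values measure the spread between these samples.

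Differential expression was tested with edgeR 4.0.16 in R 4.3.3, with TMM normalization, the filterByExpr filter, which kept 31664 genes, and the quasi-likelihood F test of infected against control with no covariate. P-values were adjusted by the Benjamini-Hochberg method and genes under 0.05 were called. The common biological coefficient of variation was 30.3%. CPM values use the TMM library sizes, and the standard error of a log2 fold change was its size divided by the square root of F. Log2 CPM values for distances, principal components and correlations used a prior count of 2. Alternatives were limma-voom without and with sample quality weights (limma 3.58.1), DESeq2 1.42.0, DESeq2 size factors, upper-quartile scaling and library totals in edgeR, no filter on low counts, a mean of at least 1 CPM, a test against a fold of 1.5, 1 surrogate variable (sva 3.50.0), and each of the 20 libraries left out in turn. DESeq2 was run on all 46585 genes, without filterByExpr. After the data were seen, a fit with the share of reads outside genes as covariate and a fit without control fish 32, 35 and 40 were added.

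The spread between fish was the root mean square log2 distance of each fish to the mean of the other fish of its group, over the 500 most variable genes, and group means were compared by a two-sided permutation test with 100000 resamples, or by exact enumeration where a group had fewer than 10 fish. Library measures were compared in the same way, with adjustment over 5 measures. The position of calls was tested on 17601 tested genes of the sequences whose names carry a chromosome (chr_ and chrUn_ together) by counting adjacent gene pairs called in the same direction and permuting the calls 10000 times, two-sided. Python 3.11.15 with scipy 1.17.1, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used.

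The gene test was tested on simulated data. Counts were drawn for the 31664 genes from the means, the dispersions of single genes and the library sizes of these 20 libraries. After the same filter, 31198 genes were tested. In the simulation 100 genes were changed 2-fold and 100 genes 1.5-fold, picked among genes with a mean of at least 1 CPM. The test recovered 64% of the 2-fold and 19% of the 1.5-fold changes, and 3 of 86 calls were false (3.49%). The real data gave 12191 calls, so the adjusted cutoff was looser there, and these shares do not give the recovery in the real data. The neighbour test gave a ratio of 0.975 for random calls and 1.19 after calls were copied to 1000 neighbours, on 17601 genes.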

Results

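Transcript levels were measured in the gills of 10 control rainbow trout and 10 trout infected with Ichthyophthirius multifiliis, a ciliate parasite that burrows into the epithelium of skin and gills and causes white spot disease. The labels number the control fish 31 to 40 and the infected fish 41 to 50, and the time since exposure is not given in the sources used here. Reads in annotated genes numbered 5692204 to 10498985 in control libraries and 7564982 to 10427293 in infected libraries, and the group means differed by an amount within the spread between fish (two-sided permutation test, p = 0.269, adjusted p = 0.448 over 5 measures). Of 46585 gene models, 1550 had no read in any library. Genes are given by the ID of the deposited annotation, since the files do not pair IDs with names.

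The series' title asks how immunity in the gill responds to the parasite. Infection went with a change in a large part of the gill transcriptome. Of 31664 genes tested, 6252 were higher and 5939 lower in infected than in control gills, 12191 in all (edgeR quasi-likelihood test, adjusted p under 0.05, n = 10 per group). Genes called higher held 28.4% ± 1.46 of reads in control fish and 43.7% ± 2.25 in infected fish (SD, n = 10), and genes called lower held 24.1% ± 3.34 and 12.98% ± 1.32. Control and infected fish lay apart on the first principal component, which carried 35.3% of the variance of the 500 most variable genes. The balance between directions depended on scaling. Library totals alone moved the median log2 fold change of all tested genes from −0.06 to −0.19. They gave 4691 genes higher and 8616 lower (35.3% higher, against 51.3% with TMM). Each change therefore stands relative to the scaling used.

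**Figure D1:**
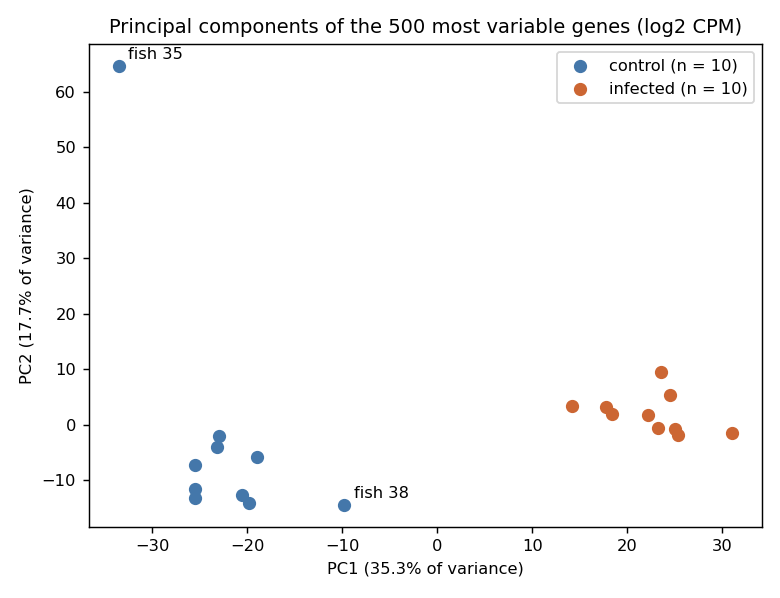
Principal components of log2 CPM over the 500 most variable genes, with 1 point per fish (blue, 10 control; orange, 10 infected). The first component (35.3% of variance) separates the groups, and control fish 35 stands alone on the second (17.7% of variance).

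Most changes were under 2-fold. At least 2-fold differences were found for 1605 genes that rose and 1280 that fell, and at least 4-fold differences for 189 that rose and 116 that fell. The 189 genes took 0.375% ± 0.151 of reads in control fish and 2.83% ± 0.861 in infected fish (SD, n = 10). In 1531 genes every infected fish was above every control fish, and in 267 genes every infected fish was below every control fish, where chance gives 0.171 genes in each direction among those tested. The numbers of large changes varied with the fish, the method and the filter on low counts. Without control fish 35 44 genes were at least 4-fold lower, and 38 of the 116 genes stayed at least 4-fold lower, whereas 178 of the 189 stayed at least 4-fold higher. DESeq2, run on all 46585 genes without the main filter, gave 304 genes at least 4-fold higher and 304 lower. Its difference from the main fit therefore mixes method and filter. DESeq2 size factors in edgeR on the filtered genes gave 185 and 121. EdgeR with a mean of at least 1 CPM as its filter gave 211 and 383. That filter tested 32943 genes, against 31664, and which fish carry the added falls was not tested. The balance of changes of at least 2-fold turned in some settings, with 1854 higher and 1938 lower by DESeq2, 1833 and 2374 in edgeR without a filter on low counts, 1641 and 1678 with a mean of at least 1 CPM, 1404 and 1580 with upper-quartile scaling, and 1245 and 1874 with library totals. All other alternatives kept more rises than falls, among them 1729 and 1194 with limma-voom and 1719 and 1254 without control fish 35.

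**Figure D2:**
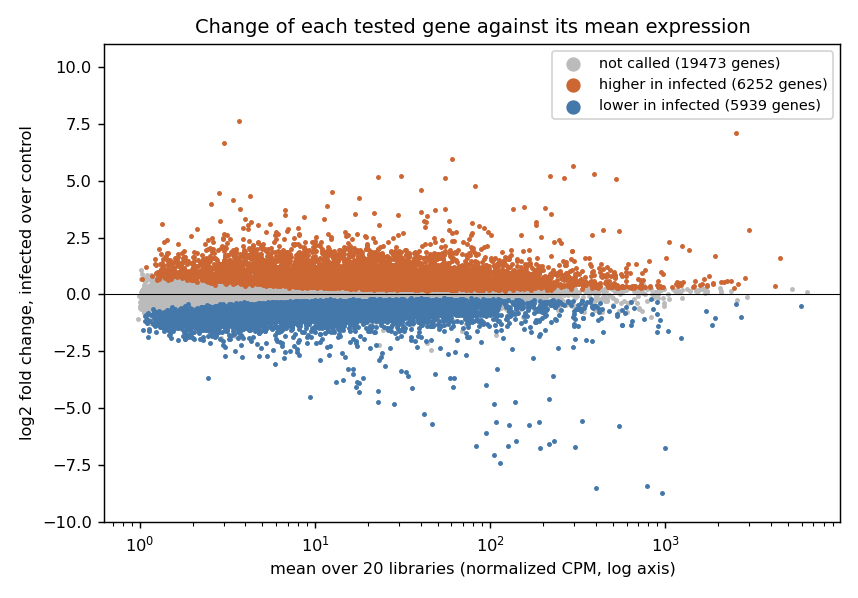
Log2 fold change of each of the 31664 tested genes (infected over control) against its mean normalized CPM on a log axis, coloured by the edgeR call (orange, 6252 higher; blue, 5939 lower; grey, not called). The points far below 0 at high expression include the genes that control fish 35 set apart.

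Among genes with a mean of at least 5 CPM, the smallest adjusted p among those that rose belonged to GSONMG00006702001, which went from 1.49 ± 0.738 CPM in control fish to 21.9 ± 4.51 CPM in infected fish (SD, n = 10), a log2 fold change of 3.88 (SE 0.21, edgeR adjusted p = 1.65e-10). Its lowest infected fish, at 17.3 CPM, stood above its highest control fish, at 2.93 CPM. The deposited annotation places it on the sequence called chrUn at 969905025 to 969907600, plus strand, with 7 coding segments and a coding length of 747 bp. GSONMG00061399001 followed, with 24.0 ± 2.90 CPM in control and 68.6 ± 8.51 CPM in infected fish, a log2 fold change of 1.51 (SE 0.087, edgeR adjusted p = 2.05e-10). It lies on chrUn_12 at 28472293 to 28478280, minus strand, with 11 coding segments and a coding length of 1575 bp. The build behind these positions is not given in the sources used here.

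Among genes that fell, GSONMG00049456001 had the smallest adjusted p, with 75.3 ± 12.7 CPM in control and 26.1 ± 4.19 CPM in infected fish (SD, n = 10), a log2 fold change of −1.53 (SE 0.11, edgeR adjusted p = 1.55e-09). Its annotated span is 47266140 to 47270308 on chrUn_8, minus strand, with 6 coding segments and a coding length of 1014 bp. GSONMG00021029001 came next, with 42.6 ± 5.61 CPM in control and 18.6 ± 2.02 CPM in infected fish, a log2 fold change of −1.19 (SE 0.089, edgeR adjusted p = 3.10e-09). Its annotated span is 44575286 to 44579249 on chrUn_11, minus strand, with 3 coding segments and a coding length of 774 bp. In both genes the highest infected fish, at 33.3 and 21.5 CPM, stood below the lowest control fish, at 61.9 and 34.1 CPM.

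**Figure D3:**
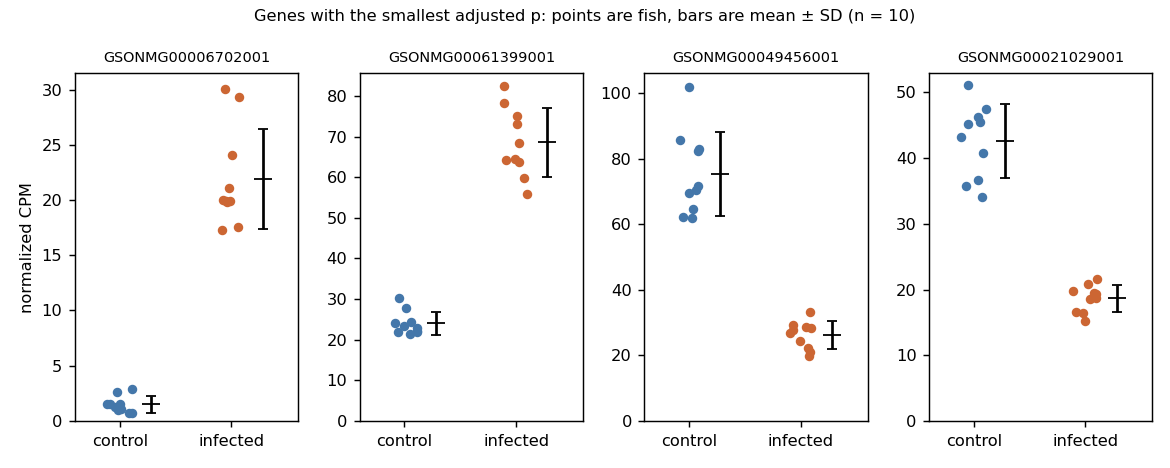
Normalized CPM per fish (points; blue, control; orange, infected) with mean ± SD (bars, n = 10 per group) for the 2 genes that rose and the 2 that fell with the smallest adjusted p; each panel has its own linear axis from 0. In each panel no infected fish overlaps a control fish.

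Fewer reads of infected gills fell outside annotated genes. The share was 33.8% ± 1.33 (SD, n = 10) in infected fish and 40.4% ± 7.42 (SD, n = 10) in control fish (two-sided permutation test, p = 0.00042, adjusted p = 0.0021 over 5 measures). Control fish 40, at 59.0%, and control fish 32, at 46.9%, had the highest shares, and the other 8 control fish averaged 37.3% ± 2.09 (exact permutation test against the infected fish, p = 0.00123). Infected libraries also had reads in fewer genes, 38801 ± 530 against 39657 ± 785 (SD, n = 10, permutation p = 0.0121, adjusted p = 0.0302). With the share outside genes as a covariate, an alternative added after the data were seen, edgeR called 4628 genes higher and 3869 lower, and without control fish 32, 35 and 40 it called 6166 higher and 5636 lower.

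Single control fish also stood apart within their group. In control fish 35, 181 of the tested genes were at least 4-fold above every other control fish. Together they took 14.9% of its reads in tested genes, against 0.213% to 0.482% in the other 19 libraries. Genes with reads in fish 35 alone would have been removed by the filter and are not in this set. In control fish 38, 13 of the 101 genes that were at least 4-fold higher in infected fish with an infected mean of at least 20 CPM were at least 2-fold above every other control fish. Those 13 genes took 0.124% of reads in fish 38, 0.00536% to 0.0158% in the other 9 control fish and 0.299% to 1.74% in infected fish.

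**Figure D4:**
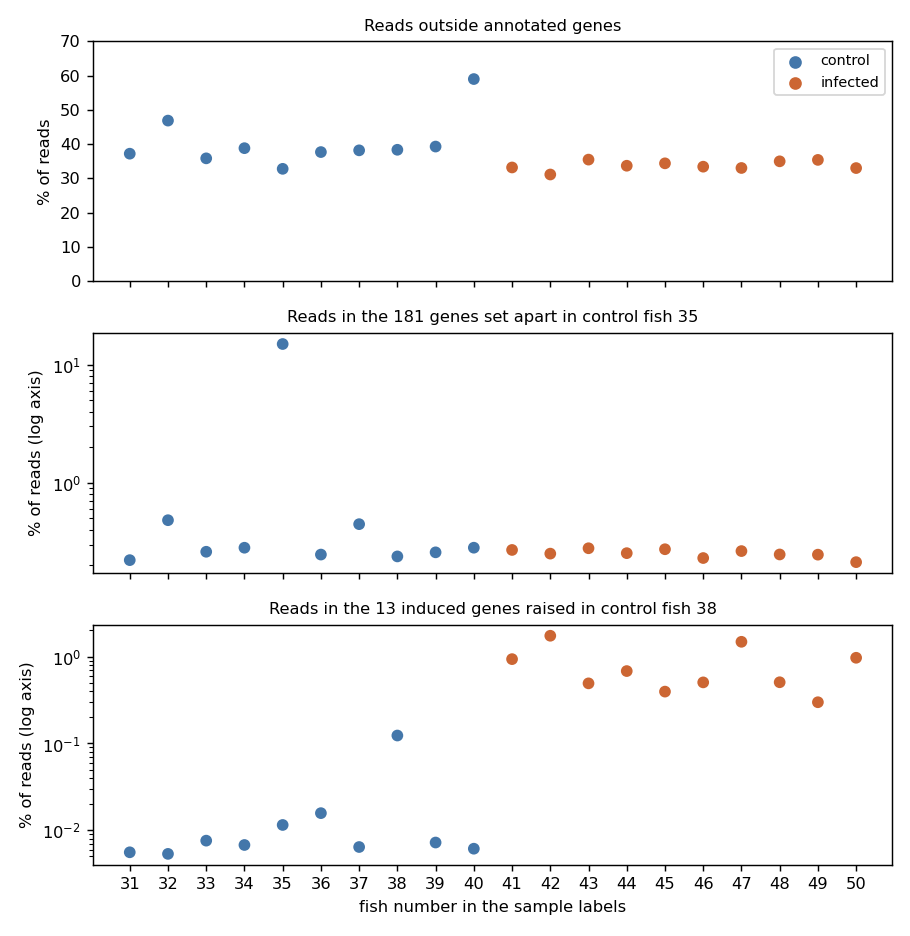
Percent of reads per fish (points; blue, control; orange, infected) outside annotated genes (top, linear axis), in the 181 genes that set control fish 35 apart (middle, log axis) and in the 13 induced genes raised in control fish 38 (bottom, log axis). Fish 40 reaches 59.0% in the top panel. Fish 35 reaches 14.9% of reads in tested genes in the middle panel. Fish 38 lies between the groups at 0.124% in the bottom panel.

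Control fish differed more among themselves than infected fish did over the 500 most variable genes, and this rested on control fish 35. The log2 distance of a fish to the mean of its group was 1.68 ± 0.62 (SD, n = 10) in control and 1.31 ± 0.14 (SD, n = 10) in infected fish, a difference of −0.37 (two-sided permutation test, p = 0.0154). Control fish 35 lay at 3.39. Without it the difference was −0.15 (exact permutation test, p = 0.0821, n = 9 control fish).

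Genes that changed together lay next to each other more often than chance. On sequences whose names carry a chromosome, most of them with the prefix chrUn_, 1996 adjacent pairs of tested genes were called in the same direction, where permuted calls gave 1431, a ratio of 1.39 (p = 0.0001, the smallest that 10000 permutations can give). Runs of at least 3 neighbouring genes that were each called and at least 2-fold changed numbered 25, of which 16 rose and 9 fell, against 3.22 on average and at most 9 in 1000 permutations. The longest run held 8 genes that fell, on the plus strand of chrUn_15 from 1575176 to 1680085, with log2 fold changes from −1.46 to −1.03, and the longest permuted run held 6. The ratio was 1.40 on the 1684 genes of sequences named chr_ alone and 1.39 on the 15917 genes of sequences named chrUn_ alone, and what this prefix says about gene order is not given in the sources used here. Of the 25 runs, 15 lay wholly on 1 strand (60%, against 33.2% of permuted runs).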

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

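The tests on control fish 35 and control fish 38 below were chosen only after the results were seen. In each group of 10 fish, the fish at either end was compared with the others for 15 kinds of value, 29 groups in all, and 8 fish values stood apart; chance gives about 1 in 20 groups. Some of these values were built from genes picked because that fish was high in them, so they describe the pattern and do not test it.

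Control fish 35 stood apart from the other control fish in the share of reads in its 10 most abundant genes (9.30%). It also did so in its log2 distance to the group (3.39) and in the second principal component (64.7). The number of tested genes at least 4-fold above the other fish of the group (181) and the share of reads in tested genes that this set took (14.9%) stood apart too. The place of the fish on an axis from the other control fish (0) to the infected fish (1), over 12591 genes outside that set, was 0.263, where the other control fish lay from −0.124 to 0.123 and infected fish from 0.832 to 1.16, which argues against a wrong group label. The other control fish set the origin and helped to choose the genes, and only fish 35 and 38 were held out in this way. Whether fish 35 shifted toward the infected fish therefore cannot be told. On the first principal component, which genes of that set can enter, it lay at −33.5, farther from the infected fish than any other control fish. The large decreases in infected fish come mostly from this library, since 38 of the 116 genes at least 4-fold lower stayed so without it and 7 of the 116 were then called higher. A single source, such as tissue or RNA of another kind that enters libraries in different amounts, may underlie the set, since its genes varied together in the other 19 libraries with a mean correlation of 0.0275, above the highest of 100 matched random lists (0.0151), but this relation is weak and the source stays open. No biological explanation was tested, because the labels give nothing that sets this fish apart.

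Control fish 38 stood apart in the number of induced genes at least 2-fold above the other control fish (13, against at most 2 in any other control fish) and in the mean log2 CPM of those genes (5.73). Its place on the axis from control to infected fish was 0.174, above the other control fish (−0.0907 to 0.102) and far below the infected fish (0.833 to 1.16), which argues against a wrong group label. Here too the other control fish set the origin and helped to choose the genes, so whether fish 38 shifted toward the infected fish cannot be told. Reads or RNA of infected fish mixed into the library would raise every induced gene by 1 share of its infected level. The median over all 101 induced genes was 0.589% (−4.45% to 0.130% in the other control fish), which allows a share of up to 3.56% (the median plus 2 SD of the other control fish). Yet 24 of the 101 genes rose above the other control fish by more than that share of the highest infected fish, against 0 to 9 in the other control fish treated alike. Of those 24 genes, 12 belong to the 13 picked because fish 38 was high in them, and outside the picked genes the excess over the other control fish is small. The case against mixing as the whole cause therefore rests mostly on the picked genes, and a small mixed share stays open. The infected means helped to choose the 101 genes, while control fish alone picked the 13 among them. In the infected fish the 13 genes had a mean correlation of 0.313, above 99.3% of random lists of 13 induced genes. After near-copies in expression were reduced to 10 genes, the values were 0.244 and 98.0%. The definition of the random lists gave no match on expression or size of change, and 6 of the 13 are among the 10 largest rises. The test therefore cannot tell this group from strongly induced genes at large. A candidate explanation remains a group of genes that are switched on together and were partly on in this fish. What switched them on stays open, since the labels give no health record or other factor for single fish.

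Infected fish 48 had 5 genes at least 4-fold above every other infected fish, where the other infected fish had 0 or 1.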

How the results depend on the processing

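The fits with the share of reads outside genes as covariate or without control fish 32, 35 and 40, the neighbour tests by strand and orientation, within expression deciles, with chrUn and on chr_ or chrUn_ sequences alone, the test without control fish 32 and 40, and the groups without overlap with each library left out or with library totals were chosen only after the data were seen. Of 32 alternatives, 31 gave a count of changed genes within 1.5 times of 12191; the test against a fold of 1.5 gave 2323 (1631 higher, 692 lower, 636 at least 2-fold lower), a stricter question by construction. The share of reads outside genes as covariate gave 4628 genes higher and 3869 lower. This share itself differed between the groups (40.4% in control and 33.8% in infected fish), so the fit cannot fully separate it from infection. How much of the fall in calls this makes up was not tested. At least 2-fold lower were 1938 genes with DESeq2 and 2374 without a filter. At least 4-fold higher were 304 with DESeq2 and 326 without a filter. At least 4-fold lower were 304 with DESeq2, 934 without a filter and 383 with a mean of at least 1 CPM. Limma-voom gave 33, quality weights 30, 1 surrogate variable 47 and leaving out fish 32, 35 and 40 gave 38. The 38 goes mostly with fish 35, and the other causes were not tested. Leaving out each library in turn gave 11201 to 12717 changed genes and 44 (without control fish 35) to 143 genes at least 4-fold lower. The difference in spread was −0.18 over 2000 genes (p = 0.0856) and −0.063 over all genes (p = 0.0646), and ran from −0.45 to −0.15 with each library left out, the last without control fish 35 (exact permutation test, p = 0.0821). The neighbour ratio kept its direction in 10 of 10 alternatives (1.16 to 1.52), and each of the 4 named genes kept its call in 32 of 32. Genes with every infected fish above every control fish numbered 1545 to 1821, and those below 279 to 358, with each library left out. These counts could only stay or rise from 1531 and 267, because the same values were compared with 1 fish fewer, so they are no check for a loss. With library totals the counts were 1093 and 366. Of 100 drawn splits of the 20 libraries, the real one included, 1 gave as many genes as the real groups, and the highest of the others gave 268. The real groups thus lay far beyond the other 99 splits drawn. Such splits cannot tell infection from another difference between the groups, such as how the fish were kept or the libraries made, which the labels do not give per group. The erythrocyte covariate and the gene list tests were not run, because no ID could be paired with a name. No paired analysis was possible because the groups share no fish number. In the simulation, with 100 genes changed 1.5-fold and 100 genes 2-fold, 19% of the 1.5-fold changes were recovered. With 12191 calls in the real data the adjusted cutoff was looser, so this share does not give the recovery there. Small changes can still be missed.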

Other observations

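The coding length test of genes at least 4-fold higher was written before its result was seen, while the coding lengths of the other lists, the shares of models with 1 coding segment, the list of the 10 largest changes, the neighbour tests by strand, orientation, expression and fold, and the runs of neighbours were chosen after the data were seen. Among called genes with a mean of at least 5 CPM, the 10 largest rises had log2 fold changes of 5.05 to 7.11, and 10 of 10 were also called higher without control fish 38, where they ranged from 5.09 to 8.61; 6 of the 10 belong to the 13 genes raised in that fish. The largest of them, picked out after its values were seen, is a gene model with 1 coding segment of 279 bp on chrUn at 604796734 to 604797012, plus strand. It went from 36.2 ± 65.0 CPM in control fish to 5005 ± 5147 CPM in infected fish (SD, n = 10, log2 fold change 7.11, edgeR adjusted p = 5.72e-06), with infected fish from 505 to 15226 CPM and control fish from 1.76 to 211 CPM, the last being fish 38. Without fish 38 its log2 fold change was 8.21. By contrast, the 10 largest falls, with log2 fold changes of −8.74 to −6.67, all belonged to the 181 genes of control fish 35, and 1 of the 10 was called lower without that fish.

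Coding lengths were compared with random lists matched on mean expression. The 189 genes at least 4-fold higher had a median coding length of 807 bp, where the random lists had a median of 945 bp (95% of 10000 lists between 834 and 1086 bp), and the 40 genes at least 4-fold lower outside the set of fish 35 had a median of 763.5 bp, within the 705 to 1260 bp of theirs, so short coding regions are not shown to be particular to genes that rose. The 1605 genes at least 2-fold higher had a median of 981 bp, within the 927 to 1023 bp of their random lists, and the 1168 genes at least 2-fold lower outside the set of fish 35 had a median of 972 bp, above the 801 to 892 bp of theirs. Gene models with 1 coding segment made up 8.99% of genes at least 4-fold higher (5.34% in random lists, above 97.8% of them) and 3.74% of genes at least 2-fold higher (5.28%, above 0.23%). Outside the set of fish 35 they made up 10% of the 40 genes at least 4-fold lower (5.54%, above 82.4%) and 6.59% of the 1168 genes at least 2-fold lower (6.82%, above 36.25%). These lists were not tested against each other. These are predicted gene models, some of which may be fragments, and the median of 807 bp does not tell short genes from fragments.

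Neighbouring genes changed in the same direction more often than permuted calls, by a ratio of 1.39, and most clearly on the same strand, where the ratio was 1.52, and 3.92 when only calls of at least 2-fold were counted, against 1.68 for such calls on opposite strands. Pieces of a split gene model, or transcription that runs on into the next gene and is counted by strand, would join genes of the same strand only, but pairs on opposite strands gave 1.23 (p = 0.0001, the smallest that the permutations can give), which argues against these as the whole cause. The strand setting of the counting is not given in the sources used here, and run-on reads counted on either strand would also reach opposite-strand neighbours, but pairs transcribed away from each other, where neither runs into the other, gave 1.16 (p = 0.0023), and calls permuted within deciles of mean expression gave 1.37, so neither run-on reads nor like expression levels account for all of it. For the larger excess on the same strand, split models, run-on reads, tandem copies and reads shared between copies stay open, as does shared regulation of neighbours; tandem copies and shared regulation were not tested.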
